A study of Mus musculus with 6 samples.

How the data were processed

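RNA from 6 samples of Melan-Ink4a cells, 3 with NRG1 and 3 untreated, was measured on Affymetrix Mouse Gene 1.0 ST arrays from 200 ng of total RNA each, per the labels. The deposited table holds log2 values for which the authors named RMA and GCOS as tools, per the submitters' processing notes. RMA in its usual form corrects the background, normalizes across arrays and summarises the probes of each probe set, but its settings, the versions of both tools and the probe sets it was run on are not given in the sources used here. The log2 scale was read from the values themselves. The values lay between 2.34 and 14.6, and the array medians (6.99, 7.03 and 7.04 with NRG1, and 7.05, 7.01 and 7.07 untreated) differed slightly, so the distributions of the 6 columns were close to each other without being identical. Array signals are compressed near background and near saturation, so differences at both ends of the scale can be understated. An array has no read depth, the scanner images and probe-level signals were not used here, and 3 arrays per group set the precision, with a median standard error of 0.071 on the log2 scale for the difference of a gene.

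Groups and replicate numbers were taken from the sample titles. Each of the 6 columns of the table matched exactly 1 sample, and 0 value columns were left without a sample. Probe sets were named from the platform annotation, with symbols updated through Entrez gene numbers to the RefSeq genes of assembly GRCm38.p6, which was used for names and, in the closing section, for the chromosome of each gene and the order of neighbouring genes. Of the probe sets, 21789 had 1 gene, 1621 had several genes and 12147 were unnamed here, and 21698 matched a RefSeq gene by number. Probe sets with 1 gene were kept and the others left out of the named comparisons, and for the 998 genes with more than 1 such probe set the brightest by mean over all 6 arrays was tested, which left 19939 genes. No filter on level was applied. Its coordinates served only for that order and are not printed, since the authors' build is not given in the sources used here.

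Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 group means, 2-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene is called, and is said to have risen or fallen, where its adjusted p was under that threshold. Changes are NRG1 minus untreated on the log2 scale. The design, the alternatives, the naming rule and 29 gene lists were fixed before the data were examined. The lists covered melanocyte biology, ERBB signalling, growth, metabolism, stress and markers of other cell types, and 670 of their 709 entries were matched to a tested gene. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The rule named 16 genes of ERBB signalling and melanocyte biology, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, leaving out gene models without an ordinary symbol, and up to 3 called members per list and direction. In a list with no called member it named the member with the smallest p. It gave 146 genes, of which the text prints a part.

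The fit and the list tests were tested on simulated data with the spread of the real genes. In 20 simulations with 200 changed genes each, over 19939 genes, 98% of changes of 0.5 on the log2 scale and 100% of changes of 1 or 2 were recovered, with 0 of the wrong sign, and 6.08% of the called genes were false. Shifts of 0.3 on the log2 scale in whole lists were called in 100% of cases with a preset or an estimated correlation, and 3 and 0 of 480 unshifted lists were called. The simulated genes varied independently and the lists were drawn at random, so camera was not tested on lists whose members move together. In the real data the estimated correlation reached 0.756, in the mitosis list.

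The alternatives were quantile normalization, centring of each array on its median, leaving out the dimmest genes at 2 levels, testing all probe sets, averaging the probe sets of a gene, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array in turn, and a test against a minimum change of 1.2-fold. List medians under the normalizations and chromosome shifts with each array left out were added after the data were seen. Another background correction was not run, because it needs probe-level signals. A pseudocount was not needed, because the values are on a log scale.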

Results

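Melan-Ink4a is an immortal pigment cell line grown from the skin of C57BL/6J mice that lack the Ink4a-Arf tumour suppressor locus. NRG1, the growth factor neuregulin 1, binds the receptor ERBB3, which signals in a pair with ERBB2 and feeds the ERK and PI3K-AKT pathways. The cells were kept with 10 nM NRG1-beta1 for 21 days or left untreated, and the labels give no such time for the untreated cells. The medium contained 200 nM of the phorbol ester TPA and 200 pM cholera toxin, and RNA was taken at 90% confluence. Transcript levels were measured on Affymetrix Mouse Gene 1.0 ST arrays, 3 with NRG1 and 3 untreated, and are given as the deposited log2 values. The comparison addressed what prolonged NRG1/ERBB3 signalling does to gene expression in melanocytes. The array medians lay between 6.99 and 7.07 on the log2 scale over all probe sets, and 19939 named genes were tested. Across these genes, arrays of the same group correlated at 0.996 to 0.997 and arrays of different groups at 0.981 to 0.986. The first principal component held 76.9% of the variance and separated the 3 NRG1 arrays from the 3 untreated arrays. An array has no sequencing depth, and the precision is limited by the number of arrays. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

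NRG1-treated cells differed from untreated cells at 4168 of the 19939 genes (limma, adjusted p under 0.05), of which 2461 rose and 1707 fell. After quantile normalization of the same values the split was 2257 that rose and 2396 that fell, so that the share of rises went from 59% to 48.5%. Among the called genes, 301 rose and 83 fell by at least 2-fold, and 38 rose and 12 fell by at least 4-fold. Among genes named here the steepest rise was that of Mest, an imprinted gene for an alpha/beta-hydrolase-like protein, from 6.05 ± 0.059 to 9.69 ± 0.165 (SD, n = 3 each), which is 12.5-fold (limma, adjusted p = 2.75e-09). Probe sets without a single named gene were not ranked. Dock11, an exchange factor for the GTPase CDC42, rose by 3.63 ± 0.088 (SE) on the log2 scale, and Vsnl1, a neuronal calcium sensor, by 3.57 ± 0.065. The other large rises were those of Col28a1 (3.57), Serpina3n (3.46), Tmsb4x (3.40), Sulf2 (3.14), Adamts1 (3.12), Igfbp5 (3.05) and Ddah1 (2.97). Col28a1 encodes a collagen chain, Tmsb4x the actin-binding peptide thymosin beta 4, Sulf2 a heparan sulfate sulfatase and Adamts1 an extracellular metalloprotease. Sema6d, a transmembrane semaphorin, fell by 2.90 ± 0.061 on the log2 scale, from 9.62 ± 0.072 to 6.72 ± 0.021 (SD, n = 3 each; limma, adjusted p = 1.83e-09). Behind it came the potassium channel gene Kcnj13 (-2.60), Elobl (-2.60), the semaphorin receptor gene Plxnc1 (-2.54), Aoah (-2.50), Ogn (-2.40), Gpm6a (-2.33), Efemp1 (-2.23), Slc24a4 (-2.07) and the protein kinase C gene Prkcq (-2.04). The 3 NRG1 values lay entirely above or below the 3 untreated values for 4159 of the 4168 called genes, and for 36.7% of all genes, where chance alone gives 10%. An exact permutation test of any single gene cannot go below p = 0.1 with 3 arrays against 3. Against a minimum change of 1.2-fold (limma treat), 1225 genes passed.

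**Figure D1:**
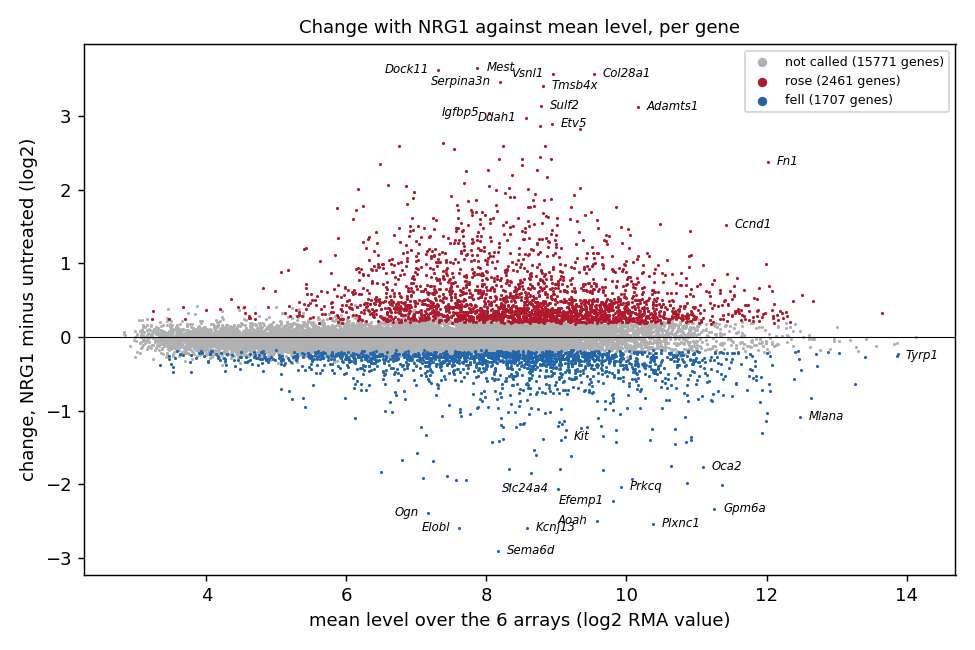
Change of each of the 19939 tested genes with NRG1 (log2, NRG1 minus untreated, vertical axis) against its mean level over the 6 arrays (log2, horizontal axis), with called rises in red, called falls in blue and other genes in grey. Of the called genes 2461 rose and 1707 fell, and the labelled extremes run from Mest at 3.65 to Sema6d at -2.90.

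Transcripts of the receptors for NRG1 did not pass the test, while 13 of 26 output and feedback genes of the ERK pathway rose. Erbb3 was at 11.72 ± 0.016 with NRG1 and 11.58 ± 0.037 without (SD, n = 3 each), a difference of 0.15 ± 0.057 (SE; limma, adjusted p = 0.105). Its adjusted p ran from 0.0129 to 0.292 over 15 alternative settings, and 3 of these called it. The log2 differences were -0.14 for Erbb2, 0.021 for Egfr, -0.15 for Erbb4 and -0.093 for Nrg1 itself, none of them called. Egfr, Erbb4 and Nrg1 had low mean levels of 6.05, 6.31 and 6.10, under the lowest array median of the tested genes (7.11). A difference in these 3 could therefore be understated. Erbb2 passed under quantile normalization only, at -0.20 (limma, adjusted p = 0.0428, in a range from 0.0428 to 0.399 over 15 settings). None of the 14 measured ERBB receptors and ligands was called by limma, either over all genes or adjusted over the list alone. The nearest to the threshold was the ligand gene Hbegf at 0.18 (limma, adjusted p = 0.0724), which 3 of 15 settings called, in a range from 0.0221 to 0.2. At an unadjusted p under 0.05 there were 4 of them, 2 up and 2 down, and fry's test for change in either direction gave adjusted p = 0.000385. In the ERK list 13 genes rose, 1 fell and 12 were not called, and 14 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 1.22e-07). That list had an adjusted p = 0.155 with an estimated correlation. Etv5, an ETS transcription factor gene induced by ERK, rose 7.43-fold, from 7.48 ± 0.055 to 10.38 ± 0.059 (SD, n = 3 each; limma, adjusted p = 1.85e-09). Ccnd1, which encodes the G1 cyclin D1, rose by 1.52 ± 0.073 (SE), and the feedback inhibitor gene Spry1 by 1.30 ± 0.09. Myc fell by 0.28 (limma, adjusted p = 0.0141), a call that ended without NRG1 replicate 3 (-0.25, adjusted p = 0.0611, in a range from 0.00141 to 0.0611 over 15 settings). Of 18 targets of the FOXO factors, which AKT keeps out of the nucleus, 3 rose and 10 fell, and 3 rose and 11 fell adjusted over the list alone (camera, adjusted p = 0.0116). The value was adjusted p = 0.488 with an estimated correlation, and camera's call also ended without untreated replicate 2 (adjusted p = 0.0542). Sesn3 fell by 0.74, Cited2 by 0.58 and the pro-apoptotic Bcl2l11 by 0.50, while Foxo1 rose by 0.94 and the insulin receptor substrate gene Irs1 by 0.40.

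Pigment genes were lower with NRG1. Of 32 measured genes of the melanosome and of pigment synthesis, 25 fell and 2 rose, the same numbers as when adjusted over the list alone, with a median of -0.49 on the log2 scale (camera, adjusted p = 7.15e-14). This became adjusted p = 0.155 with an estimated correlation. The steepest falls were those of Atp6v0d2, a proton pump subunit gene (-1.90), of Oca2, which encodes a melanosomal anion transporter (-1.77 ± 0.072, SE), and of the melanosomal receptor gene Gpr143 (-1.53). Mlana, the Melan-A gene, fell by 1.09 ± 0.078, from 13.03 ± 0.078 to 11.93 ± 0.129 (SD, n = 3 each; limma, adjusted p = 4.62e-06). Pmel, which encodes the protein of the melanosome fibrils, fell by 0.64 (limma, adjusted p = 2.96e-05). The enzymes of melanin synthesis fell by less, with Tyr at -0.45 (limma, adjusted p = 0.000274), Tyrp1 at -0.26 (adjusted p = 0.00804) and Dct at -0.23 (adjusted p = 0.0136). The Dct call ended after quantile normalization (-0.085, adjusted p = 0.25), without NRG1 replicate 1 (adjusted p = 0.0594) and without untreated replicate 1 (adjusted p = 0.0536), in a range from 2.96e-05 to 0.25 over 15 settings. Tyrp1 and Dct had mean levels above 13, where the 16 genes measured had a median absolute change of 0.135, against 0.215 for 334 genes at 11 to 13. The melanocortin receptor gene Mc1r and the copper transporter gene Atp7a were the 2 members that rose, by 0.32 and 0.39.

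**Figure D2:**
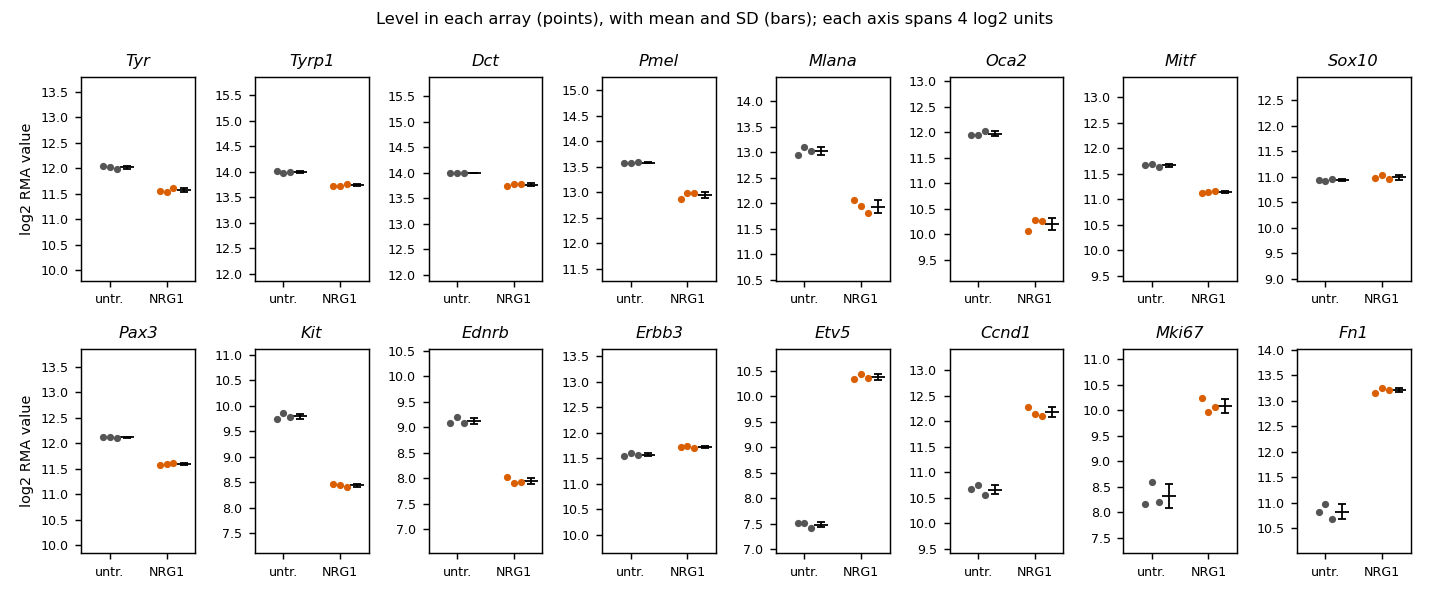
Level of 16 named genes in each array (points; log2 scale, each axis spanning 4 units) with the group mean and SD beside them, untreated in grey and NRG1 in orange. Mlana, Oca2, Kit and Ednrb sit lower in every NRG1 array, Etv5, Ccnd1, Mki67 and Fn1 higher, and Sox10 was not called.

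Regulators of the melanocyte lineage moved in both directions. Of 20 measured, 8 fell and 2 rose, and 9 fell and 3 rose adjusted over the list alone (camera, adjusted p = 0.00423, and adjusted p = 0.38 with an estimated correlation). Kit, the receptor for stem cell factor, fell 2.56-fold, from 9.79 ± 0.053 to 8.44 ± 0.03 (SD, n = 3 each; limma, adjusted p = 1.59e-07). The endothelin receptor gene Ednrb fell by 1.17 (limma, adjusted p = 6.73e-07) and the transcription factor gene Pax3 by 0.53, and Tfap2b fell 2.29-fold. Mitf, the central transcription factor of the lineage, fell from 11.67 ± 0.037 to 11.14 ± 0.018 (SD, n = 3 each; limma, adjusted p = 8.51e-05), a change of -0.53, and its second probe set gave -0.62. Sox10, which acts upstream of Mitf, was not called, at 0.056 (limma, adjusted p = 0.565). Lef1, whose product partners with beta-catenin, rose by 1.04, and the E-protein gene Tcf4 by 0.48. Cdkn2a, at the locus the line lacks, was at 7.44 ± 0.073 with NRG1 and 7.53 ± 0.035 without (SD, n = 3 each; limma, adjusted p = 0.379). Which of its exons the probes cover is not given in the sources used here, so that value is no check on the deletion.

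Nearly all measured genes of cell division rose with NRG1. All 34 measured genes of mitosis rose, with a median of 1.30 on the log2 scale (camera, adjusted p = 2.05e-32, and adjusted p = 0.155 with an estimated correlation), and all 34 adjusted over the list alone. Of 35 genes of DNA replication, 32 rose and 0 fell by both counts, with a median of 0.66 (camera, adjusted p = 2.13e-23, and adjusted p = 0.155 with an estimated correlation). Mki67, the proliferation marker gene, rose 3.39-fold from 8.32 ± 0.232 to 10.08 ± 0.144 (SD, n = 3 each; limma, adjusted p = 2.23e-06). Anln, needed for cytokinesis, rose by 1.76 and the spindle checkpoint kinase gene Bub1 by 1.73. In the replication list, Uhrf1, which helps to copy DNA methylation, rose by 1.45, the ribonucleotide reductase gene Rrm2 by 1.40 and the helicase gene Mcm3 by 1.32. Of 22 CDK inhibitors and p53 targets, 7 rose and 0 fell by both counts, among them Plk2 (1.80), Phlda3 (0.73) and Eda2r (0.50) (camera, adjusted p = 0.00597). For that list the value was adjusted p = 0.155 with an estimated correlation, and 11 members passed at an unadjusted p under 0.05, 10 up and 1 down. Leaving out the genes below the median level also ended its call (camera, adjusted p = 0.0994).

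Adhesion genes rose as a group. Of 29 integrins and partners in matrix adhesion, 20 rose and 1 fell, and 23 rose and 1 fell adjusted over the list alone, with a median of 0.80 on the log2 scale (camera, adjusted p = 2.48e-15, and adjusted p = 0.155 with an estimated correlation). The matrix protein gene Thbs1 rose 5.36-fold (limma, adjusted p = 2.75e-08), and the collagen-binding integrin genes Itga1 and Itga2 by 1.96 and 1.77 on the log2 scale. Alcam, a cell-cell adhesion molecule, fell by 1.76 ± 0.057 (SE; limma, adjusted p = 2.03e-08). Among 25 genes of epithelial-mesenchymal transition, 9 rose and 3 fell, and 9 rose and 4 fell adjusted over the list alone (camera, adjusted p = 0.0303, and adjusted p = 0.155 with an estimated correlation). Its median change was 0.007, and -0.005 when each array was centred on its median. The call of the list also ended with array weights (adjusted p = 0.0851), without untreated replicate 2 (adjusted p = 0.142) and with the dimmer genes left out (adjusted p = 0.0994). Fn1, the fibronectin gene, rose from 10.83 ± 0.15 to 13.21 ± 0.045 (SD, n = 3 each), 5.22-fold, the matrix gene Tnc rose by 2.05 and the growth factor gene Tgfb2 by 1.19, while the E-cadherin gene Cdh1 fell by 0.45. The other falls were those of mesenchymal genes, Vim, the vimentin gene, by 0.28 (limma, adjusted p = 0.0048) and the transcription factor gene Snai2 by 0.34 (adjusted p = 0.0494). The Vim call ended after quantile normalization (-0.10, adjusted p = 0.174), and the Snai2 call under 6 of 15 settings, 5 of them fits without a single array (adjusted p from 0.0106 to 0.128 over the 15), with a change of -0.205 without untreated replicate 2. From the list of the undifferentiated melanoma state, 7 of 21 genes rose and 2 fell, and 8 rose and 2 fell adjusted over the list alone (camera, adjusted p = 0.00796, and adjusted p = 0.169 with an estimated correlation). Its largest rises were those of the AP-1 gene Jun (1.60), the matrix signalling gene Ccn1 (1.22) and the TWEAK receptor gene Tnfrsf12a (0.65), and Wnt5a and Tead4 both fell by 0.35.

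Schwann cells share a neural crest origin with melanocytes and depend on NRG1. Of 20 measured Schwann cell and glial markers, 8 rose and 1 fell by both counts, over all genes and adjusted over the list alone (camera, adjusted p = 0.0229, and adjusted p = 0.155 with an estimated correlation). The intermediate filament gene Nes rose 3.09-fold (limma, adjusted p = 1.10e-07), the neurotrophin receptor gene Ngfr by 0.65 on the log2 scale and Cnp by 0.63. The marker that fell was S100b, a calcium-binding protein gene of Schwann cells and melanocytes, by 0.27 (limma, adjusted p = 0.0185), a call that ended without NRG1 replicate 3 (adjusted p = 0.0791) and with all probe sets tested (adjusted p = 0.052). The call of the list also ended without untreated replicate 2 (adjusted p = 0.0709) and with the dimmer genes left out (adjusted p = 0.289). Neuronal genes were not called as a list (camera, adjusted p = 0.919), and 2 of 19 rose and 1 fell by both counts, including rises of Uchl1 by 1.79 and of Tubb3 2.30-fold. Of 36 axon guidance receptors and ligands, 11 rose and 4 fell, and 11 rose and 5 fell adjusted over the list alone, without a shift of the list (camera, adjusted p = 0.169). Sema6a rose by 1.86, Efnb2 by 1.55 and Sema3e by 1.48, whereas Sema6d and Plxnc1 were among the steepest falls of the named genes. Neither Wnt targets (4 of 17 rose and 4 fell by both counts; camera, adjusted p = 0.915) nor Notch targets (3 of 18 rose and 1 fell, and 4 and 1 adjusted over the list alone; camera, adjusted p = 0.421) shifted as lists. Nkd2, an inhibitor of Wnt signalling, rose by 1.26 and Hes1, a Notch-induced repressor, by 1.71, while Tnfrsf19 fell by 1.02 and the Wnt feedback gene Axin2 by 0.53.

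Metabolic genes rose in several groups. Of 24 genes of glycolysis and the hypoxia response, 15 rose and 2 fell, and 16 rose and 2 fell adjusted over the list alone, with a median of 0.51 on the log2 scale (camera, adjusted p = 3.89e-09, and adjusted p = 0.155 with an estimated correlation). Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, rose by 1.32 ± 0.093 (SE) and the peptide hormone gene Adm by 1.11. Bnip3 rose by 1.69, and by 0.70 on its other probe set. Against the direction of the list, Ndrg1 fell 2.64-fold (limma, adjusted p = 1.26e-07). Of 26 genes of the amino acid starvation and ER stress response, 16 rose and 3 fell, and 17 rose and 3 fell adjusted over the list alone (camera, adjusted p = 2.48e-07, and adjusted p = 0.17 with an estimated correlation). Asns, the asparagine synthetase gene, rose by 1.76, the stress-induced Atf3 by 0.94 and the ER chaperone gene Hspa5 by 0.81. The 3 falls were those of the amino acid transporter gene Slc3a2 by 0.57, of Slc7a11 by 0.41 and of Ddit3 by 0.38. The call of Slc7a11 ended under 7 of 13 alternative settings and that of Ddit3 under 4 of 15. In the list of ribosome biogenesis and MYC targets, 11 of 25 genes rose and 3 fell, and 14 rose and 3 fell adjusted over the list alone (camera, adjusted p = 0.000402, and adjusted p = 0.38 with an estimated correlation). The transferrin receptor gene Tfrc rose by 1.64 and the polyamine enzyme genes Odc1 and Srm by 0.76 and 0.69, but the nucleolar gene Npm1 fell by 0.33 and Polr1c by 0.29.

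Cholesterol synthesis, respiration and the lysosome showed smaller differences. Of 19 cholesterol genes 5 rose and 0 fell, and 9 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.0493), including Stard4 (0.33) and Sqle (0.31). That list had an adjusted p = 0.588 with an estimated correlation and lost its call under 11 of 16 alternatives, among them quantile normalization (adjusted p = 0.293) and the fit without NRG1 replicate 1 (adjusted p = 0.202), untreated replicate 1 (adjusted p = 0.111) or untreated replicate 3 (adjusted p = 0.122). Of 30 nuclear genes of oxidative phosphorylation 6 rose and 2 fell by both counts, among them the cytochrome c gene Cycs (0.70) and Cox5a (0.36) (camera, adjusted p = 0.0729). The other probe sets of Cycs gave 0.73 and 0.076. This list was called with array weights (adjusted p = 0.0234) and without NRG1 replicate 2 (adjusted p = 0.0371), NRG1 replicate 3 (adjusted p = 0.0354) or untreated replicate 2 (adjusted p = 0.00678). Of 29 lysosomal genes, 11 fell and 3 rose by both counts, without a shift of the list (camera, adjusted p = 0.147). The cathepsin gene Ctsf fell by 1.03, Tpp1 by 0.46 and Npc2 by 0.42, and the lipase gene Lipa rose by 1.11.

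Interferon-response genes were lower with NRG1, while those of acute stress were higher. Of 20 measured interferon-response genes, 11 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone, with a median of -0.27 on the log2 scale (camera, adjusted p = 2.4e-05, and adjusted p = 0.155 with an estimated correlation). Ifit3 fell 2.67-fold (limma, adjusted p = 1.83e-07), Ifit1 by 0.84 on the log2 scale and Rsad2 by 0.60, all of them antiviral effector genes, and the RNA sensor gene Ddx58 rose by 0.57. NF-kappaB-driven cytokine and inflammation genes were not called as a list (camera, adjusted p = 0.385), with 1 of 24 that rose and 3 that fell by both counts. Lif, a cytokine of the interleukin-6 family, rose by 0.41, and the cytokine gene Il1a fell by 0.29. Their mean levels of 6.30 and 4.26 lay under the lowest array median of the tested genes (7.11). The difference of Il1a in particular may lie in the range of background. In the list of immediate stress and heat shock, 11 of 22 genes rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.000119, and adjusted p = 0.155 with an estimated correlation). That list also holds Jun and Atf3. The chaperone gene Hsp90aa1 rose by 0.56 and Hspa1a fell by 0.40.

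Markers of fibroblasts, keratinocytes, leukocytes and endothelium showed no common rise. Of 20 fibroblast markers 4 rose and 0 fell, and 4 rose and 2 fell adjusted over the list alone, with a median of -0.008 (camera, adjusted p = 0.169). The directional test of fry called that list (adjusted p = 0.0437). Its risers included the matrix genes Postn (1.88), Col1a1 (0.86) and Col5a1 (0.61). None of 19 keratinocyte markers passed limma's test by either count, or at an unadjusted p under 0.05 (camera, adjusted p = 0.385), and the nearest was Krt17 at -0.20 (limma, adjusted p = 0.206). Among 14 macrophage and leukocyte markers 1 rose, and 0 were called adjusted over the list alone (camera, adjusted p = 0.915). Of 12 endothelial markers 1 rose and 2 fell by both counts (camera, adjusted p = 0.164), with the TGF-beta co-receptor gene Eng at 0.62 and Egfl7 at -0.34. Of all 29 lists camera called 17, 13 up and 4 down, and array means did not overlap between the groups in each of the 17 and in 24 of all 29. With an estimated correlation camera called 0 of the 29, with 7 at an unadjusted p under 0.05, and fry called 17, of which 16 were shared with camera. The median and camera's direction differed in sign for the neuronal, fibroblast and axon guidance lists, and fry and camera differed in sign for the Wnt list.

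**Figure D3:**
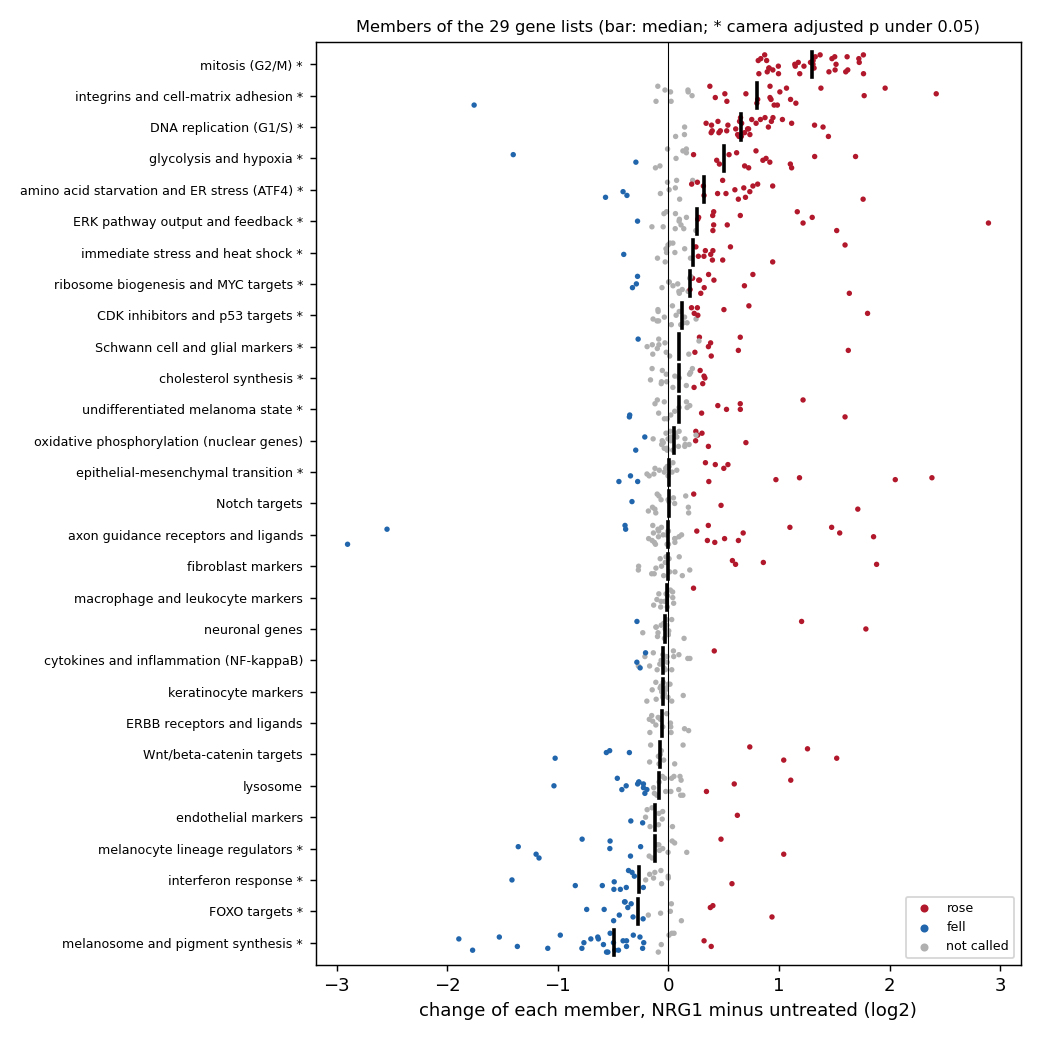
Change of every measured member of the 29 gene lists (points; log2, NRG1 minus untreated), coloured red for called rises, blue for called falls and grey otherwise, with each list's median as a black bar and an asterisk where camera's adjusted p was under 0.05. All 34 mitosis genes lie to the right of 0, and 25 of 32 pigment genes are called falls.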

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

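In this part the test of other cell types was chosen after the result was seen, and the other tests before. The preset rule of the growth state test was set aside, as given below. Genes outside the fixed lists were named after their values were seen.

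A total of 61 probe sets unnamed here, of 12147, were called and changed at least 2-fold. They were set apart because the comparisons of named genes do not use them. Of these, 27 rose and 34 fell, with the largest changes at 3.76 and -2.41 on the log2 scale, and 1128 of the unnamed probe sets were called at any size. In the same way 22 of the 1621 probe sets that cover several genes were called and changed at least 2-fold, 18 up and 4 down, from 1.27 to -1.20, and 209 were called at any size.

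Of 32 pigment genes 25 fell with NRG1. The medians argue against dilution by fibroblasts, keratinocytes, leukocytes or endothelial cells, since the highest among their marker lists was -0.008. Over these 65 markers 6 rose and 2 fell, although fry called the fibroblast list up (adjusted p = 0.0437). Schwann cell markers, called up by camera (adjusted p = 0.0229, and 0.155 with an estimated correlation), were not part of this test. The 14 genes most specific to melanocytes also ranged from -1.77 (Oca2) to 0.32 (Mc1r), with an SD of 0.60 against a median standard error of 0.059. A lower share of melanocytes on its own would move them alike. This spread does not exclude some dilution beside other changes. Compression of the brightest signals stays open for the small falls of Tyrp1 and Dct: genes at a mean of 13 or more had a median absolute change 0.628 times that of genes at 11 to 13 (0.135 over 16 genes against 0.215 over 334), between the bounds set for either answer, and Pmel was the only such gene to change by 0.5 or more. A response of the pigment programme to NRG1 may underlie the larger falls, but this hypothesis was not tested. A difference in density or passage that follows the groups cannot be told apart from it by these 6 arrays.

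Genes of mitosis had the largest median rise of the 29 lists, and 32 of 35 replication genes rose. Growth state that varied between single cultures stays open. The gap between the groups was 2.51 times the wider range within a group, which the rule set before the test counted against it. That rule was set aside, because the arrays of a group may share a culture, so that range cannot measure how cultures vary. The means over 69 genes of mitosis and replication were 0.66, 0.36 and 0.43 with NRG1 and -0.53, -0.39 and -0.54 untreated, each gene centred on its mean. Whether the NRG1 cultures were taken at another density or passage from the untreated ones cannot be separated from the treatment by these 6 arrays, as both groups are given as 90% confluent and no growth measurement was used here. Faster division under NRG1 may therefore be one reading, and a difference in culture history that follows the groups another, and the latter was not tested.

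The rise of glycolysis and hypoxia genes had an open explanation in low oxygen acting through HIF. HIF targets outside the fixed lists had a median change of 0.188, between the bounds of 0.3 and 0.1 set for either answer. Of these 26 genes 12 rose and 2 fell (camera, p = 4.69e-05, and p = 0.0279 with an estimated correlation), with Lox at 1.21, Fam162a at 0.74 and Ero1a at 0.71, but Rora at -0.54 and Ak4 at -0.37. Several of the targets, such as Lox, are also matrix genes, and matrix and growth genes rose as well, so the test does not separate oxygen from growth signalling. Denser or faster growing cultures may use more oxygen, which was not measured here.

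The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and in each case 1 split, the real one, gave a result as large. The real split gave 4168 genes, 384 genes changed at least 2-fold and 17 lists, against a highest other value of 0, 0 and 10. The other splits each part the groups unevenly and keep some of the treatment difference, and camera at the preset correlation called 1 to 10 lists in each of them, although limma called 0 genes (at most 1206 at an unadjusted p under 0.05, against 6378 in the real split).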

How the results depend on the processing

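Leaving out single arrays in the chromosome test and the list medians under the normalizations were chosen after the data were seen, and the other alternatives before. Genes called numbered 4168, between 3608 and 6086 under the other settings of the same test, of which array weights, giving untreated replicate 1 a weight of 3.43 and replicate 2 of 0.423, made the most. Without single arrays the range was 3116 to 4397. The test against a minimum change of 1.2-fold called 1225 genes by its own construction. Genes changed at least 2-fold numbered 384, from 320 to 497 under other settings and 361 to 400 without single arrays. Lists called numbered 17, from 13 to 17 under other settings and 15 to 18 without single arrays, but 0 with an estimated correlation, which admits the correlation between members; 7 passed at an unadjusted p under 0.05 and fry called 17. Chromosome shifts were run in the reported fit, without the dimmest genes, without single arrays and with an estimated correlation only, and camera called 0 of 20 in each (at an unadjusted p under 0.05, 0 in the reported fit, 1 without the dimmest genes and 1 without NRG1 replicate 1). With the replicate block 3608 genes, 384 genes at 2-fold and 17 lists were called, 3526 of the genes shared, and the block ended the calls of Nfkbia, Fdps and Sdha among the named genes. Deviations of arrays of the same number from their group means correlated at -0.095, -0.164 and 0.074, and NRG1 replicate 1 correlated best with untreated replicate 2 (0.247). Centring within groups makes the correlations of an array with the other group nearly cancel. These values therefore neither show nor exclude a pairing by number. Quantile normalization kept 3766 of the 4168 calls. Over the settings, 2079 of the values of the 146 named genes kept their side of the threshold, 81 lost the call, 7 gained it and 0 reversed. For the lists 424 kept their side, 34 lost the call, 5 gained it and 0 reversed, and the cause was not tested. A change of sign counted as a reversal only where the reported fit or the alternative passed the threshold. For lists the sign was camera's direction, and a list median could change sign, as for the Schwann list with the dimmer genes left out (-0.02). Of the named genes 18 lost a call somewhere, and of the lists called 5 did so under a setting other than the estimated correlation. Dim genes are limited by signal over background, which cannot be given per array without the probe-level signals, not used here.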

Other observations

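In this part the test without histone genes was chosen after the result was seen, and the others before. The rule for the copy number test was made stricter after its result was seen, and the preset rule of the Schwann cell test was set aside. The genes named here, except Dock11 and Pdk1, fall outside the naming rule and were chosen after their values were seen.

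That gene families sharing a symbol stem, outside the fixed lists, move together was tested as a hypothesis. Of 285 families with at least 8 members, 11 were called by camera at the preset correlation, 9 of them up. With an estimated correlation camera called 0 of them (4 at an unadjusted p under 0.05, smallest adjusted p = 0.968), so the hypothesis rests on the preset correlation. The regulatory subunits of the proteasome, which degrades tagged proteins, had 10 of 14 genes that rose and 0 that fell (Psmd, median 0.31, camera, adjusted p = 0.00141), among them Psmd14 by 0.50 and Psmd7 by 0.46. Of the alpha subunits of its core 5 of 8 genes rose (Psma, median 0.33, adjusted p = 0.0304), including Psma7 by 0.43, but the family of the beta subunits of the core was not called (Psmb, 4 of 11 rose, median 0.073, and 0.012 after quantile normalization, adjusted p = 0.407). Nuclear pore genes followed (Nup, 10 of 20 rose, 0 fell, adjusted p = 0.00145), with Nup93 at 0.67 and Nup205 at 0.65. The Dock family of exchange factors for small GTPases was called on 4 of its 10 genes (adjusted p = 0.00146): Dock11 (3.63), Dock10 (2.27), Dock3 (1.15) and Dock9 (0.38). Of 9 genes with the caspase stem 6 rose and 1 fell (Casp, adjusted p = 0.0268). Casp12 rose by 2.20, Casp1 by 0.87, Casp4 by 0.70, Casp8 by 0.46, Casp8ap2 by 0.32 and Casp6 by 0.29, whereas Casp9 fell by 0.26. The Rps family, mostly proteins of the small ribosomal subunit but also some S6 kinases, was called down, with 6 of 31 that fell and 0 that rose (adjusted p = 0.0315). The Rpl family, which holds those of the large subunit, was not called (2 of 36 fell, median -0.095, adjusted p = 0.157). Of the Zkscan zinc finger genes 6 of 11 fell (adjusted p = 0.0425). Ints, Fkbp, Tspan and Rad genes were the other families called up. The median directions of the 11 called families held under quantile normalization and centring.

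Histone genes were in no fixed list. Of 28 genes above the median level taken for histone genes by their symbols, 18 rose and 1 fell, with a median of 0.41 on the log2 scale. Among them were the linker histone genes H1f5 (1.44) and H1f1 (1.42). The symbol rule also took in H13 (0.14, not called), which is not a histone gene. The 28 genes were examined because 14 of them, 12 of which rose, sat in the run of 25 neighbouring genes with the largest shift. Hfe and Abt1 in the same run fell by 0.43 and 0.26. Of the 14 genes outside the run, H13 included, 6 rose and 1 fell, with a median of 0.18.

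A copy number difference between the cultures was tested as a hypothesis for such runs. Among 9944 genes above the median level, the largest median shift of 25 neighbours was 0.345 on the log2 scale, over the 0.29 that 95% of 1000 shuffles of the gene order stayed under (permutation p = 0.005), with 15 genes of the run that rose and 4 that fell. Without the 28 genes taken for histones the largest run shifted by 0.33 (95% of shuffles under 0.283, permutation p = 0.00599). It was another run, so this test does not address the first. In the first run 12 of the 15 genes that rose were histone genes. Of its other genes Sox4 (0.91), E2f3 (0.46) and BC005537 (0.23) rose, but Hfe, Carmil1, Abt1 and Acot13 fell. The shift of the first run thus rested mostly on its histone genes. That other run, around Psmd14, Itga6, Pdk1 and Spc25, held 15 genes that rose and 1 that fell (Cers6, -0.30), and 7 of its 25 genes were below 0. A gain of the whole segment would raise its genes alike, but neighbouring genes can also share regulation, and with members that moved against the run a copy number difference may be neither taken nor dismissed from these arrays. No whole chromosome of 20 shifted (camera, smallest adjusted p = 0.94, 0 at an unadjusted p under 0.05).

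A shift of expression towards Schwann cells was tested on 42 Schwann cell and other glial or neural genes, not all particular to Schwann cells. The set lay outside the fixed lists and outside the named genes, which had been picked by their change. Of the 42 genes, 8 rose and 3 fell. Their median change was 0.004 (camera, unadjusted p = 0.127), while the fixed Schwann list was called up (8 of 20 rose, camera, adjusted p = 0.0229, and adjusted p = 0.155 with an estimated correlation). The rule set before the test counted such a median and camera p of the 42 genes against the shift. It was set aside, because a set that leaves out genes by their change excludes nothing, so the hypothesis stays open. Cadm4 (1.37), Matn2 (1.03), Megf10 (0.98) and Sox4 (0.91) were among the genes that rose.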
